A study of Caenorhabditis elegans with 16 samples.

How the data were processed

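RNA of whole N2 worms was sequenced in 16 libraries, 9 of control worms (HT115 bacteria with an empty vector) and 7 of atp-2 RNAi worms. Per the labels' protocols, RNA was extracted with GENEzol and libraries were made with a strand-specific SureSelect kit. Per the submitters' processing notes, bcl2fastq 2.20, TopHat and Cufflinks were used with the genome build WBcel235. The versions of TopHat and Cufflinks, the annotation release, the program that gave the TPM and the strand setting of the counting are not given in the sources used here. The authors' deposited tables hold TPM per library, as the file headers name them, in which each library sums to a fixed total. A gene with no signal is listed in them as 0.0001, which was set to 0. The authors also deposited a log2 ratio of mean TPM, atp-2 RNAi over control, for each gene, per the file headers. The authors' p-value and q-value stand beside it per the file headers, from a test that is not named. These log2 ratios, p-values and q-values were used only for the counts of the authors' own calls and for their log2 ratio of atp-2. A few gene symbols in the deposited tables had been turned into dates, with the gene identifiers intact.

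Depth is unknown, since TPM keep no totals, so no counting interval or detection limit could be given. Coordinates are those of the deposited tables, because the reference annotation at hand shares 46817 of the genes but has identical coordinates for only 69.1% of them. Levels at 0 hr and 20 hr come from separately made tables.

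The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. That plan assumed FPKM. The files hold TPM, so the test for normalized values was used in place of one for counts, and alternatives that need counts were not run. At 0 hr and at 20 hr, 2 atp-2 RNAi libraries were compared with 3 controls by limma 3.58.1 in R 4.3.3, on log2(TPM + 1), with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Genes with a mean of at least 1 TPM over the libraries of the table were tested. The difference between both changes was tested as an interaction in a fit of all 10 libraries. Samples were not treated as paired. In simulated data, 100 genes were changed 2-fold and 100 genes 4-fold, with independent noise between genes. Among 14094 genes at 0 hr the fit recovered 68% of 2-fold and 99% of 4-fold changes with 13 false calls. Among 12916 genes at 20 hr it recovered 70% and 100% with 18 false calls. Far more genes were called in the real data, which moves the adjusted threshold, so these figures do not describe the real comparisons. For the unreplicated pairs, log2 ratios of TPM + 1 were counted at 2-fold, with no test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these counts and the figures.

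There were 52 gene lists, written by name and covering the target, mitochondria, stress, metabolism, immunity, neurons, cuticle, germline, tissues and core machinery. Lists of at least 5 tested genes were compared with the other genes by camera, a set test in limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists. In unreplicated pairs, a list's median was set against the central 95% of 10000 random lists of the same size matched on mean expression in 20 bins. Members of a list were also adjusted over the list alone. The median change of neuronal genes was compared with those of intestine, body wall muscle and pharynx genes by a two-sided permutation test with 100000 permutations.

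The genes named were drawn from the target, the 8 largest changes per direction past the threshold at 0 hr and 20 hr, the 6 largest per direction for the difference and in each unreplicated pair, and the 2 largest changes of each list (4 for neuronal lists). Genes named outside this rule are hsp-6, hsp-60, gpd-2 and gpd-3, chosen after their values were seen.

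Alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 TPM, a shift of all libraries to the same median, quantile normalization, the replicate number as a block, all 10 libraries in 1 fit, no intensity trend, a minimum of 2-fold, an estimated correlation and leaving out each library. Camera after quantile normalization was added after the results were seen.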

Results

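Transcript levels were measured by RNA sequencing in whole N2 worms, the standard wild-type strain of Caenorhabditis elegans. Worms were fed HT115, an Escherichia coli strain used for RNA interference by feeding, which carried either an empty vector (control) or a construct for double-stranded RNA against atp-2. The gene atp-2 encodes the beta subunit of the mitochondrial ATP synthase. The stated aim was to find which genes of neurons matter when worms learn to avoid, and remember, what has stressed them. RNAi of atp-2 served as the disruption of a core cellular function. There were 16 libraries. At 0 hr and at 20 hr the control group had 3 libraries and the atp-2 RNAi group 2 (replicates 2 and 3). Single libraries of each group were taken at 24 hr and 36 hr, and a control library of 48 hr was paired with an atp-2 RNAi library of 54 hr. The labels do not say from what event the hours were counted, nor which time stands for memory formation or retrieval. The values were TPM, each gene's share of the transcripts of its library, for 46904 genes. They keep no record of sequencing depth, so the depth of each library is unknown. Between 10619 and 13565 genes per library lay above 1 TPM. Replicates of a group correlated at 0.9755 or more across genes on the log2(TPM + 1) scale, while the group means of control and atp-2 RNAi correlated at 0.5828 at 0 hr and 0.5062 at 20 hr. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

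The target transcript was lower in every atp-2 RNAi library than in every control library. The gene (WBGene00000229, chromosome III, 5228417 to 5230536, plus strand, WBcel235) stood at 123 ± 18.5 TPM (SD, n = 2) after atp-2 RNAi and 1995 ± 157 TPM (n = 3) in controls at 0 hr, so that 6.18% of the control level of atp-2 was left. Its log2 change was -4.01 (SE 0.14, limma adjusted p = 4.69e-07). At 20 hr atp-2 stood at 184 ± 17.9 TPM (n = 2) against 1724 ± 290 TPM (n = 3), a log2 change of -3.21 (SE 0.17, limma adjusted p = 2.11e-06), with 10.7% of the control level left. In the unreplicated pairs, atp-2 was 1043 against 2225 TPM at 24 hr (46.9% of control), 736 against 2578 TPM at 36 hr (28.5%) and 431 TPM at 54 hr against 2607 TPM in the 48 hr control (16.6%). All gene-wise tests were made with limma, with Benjamini-Hochberg adjustment, on log2(TPM + 1), which understates the change of genes with low values.

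**Figure D1:**
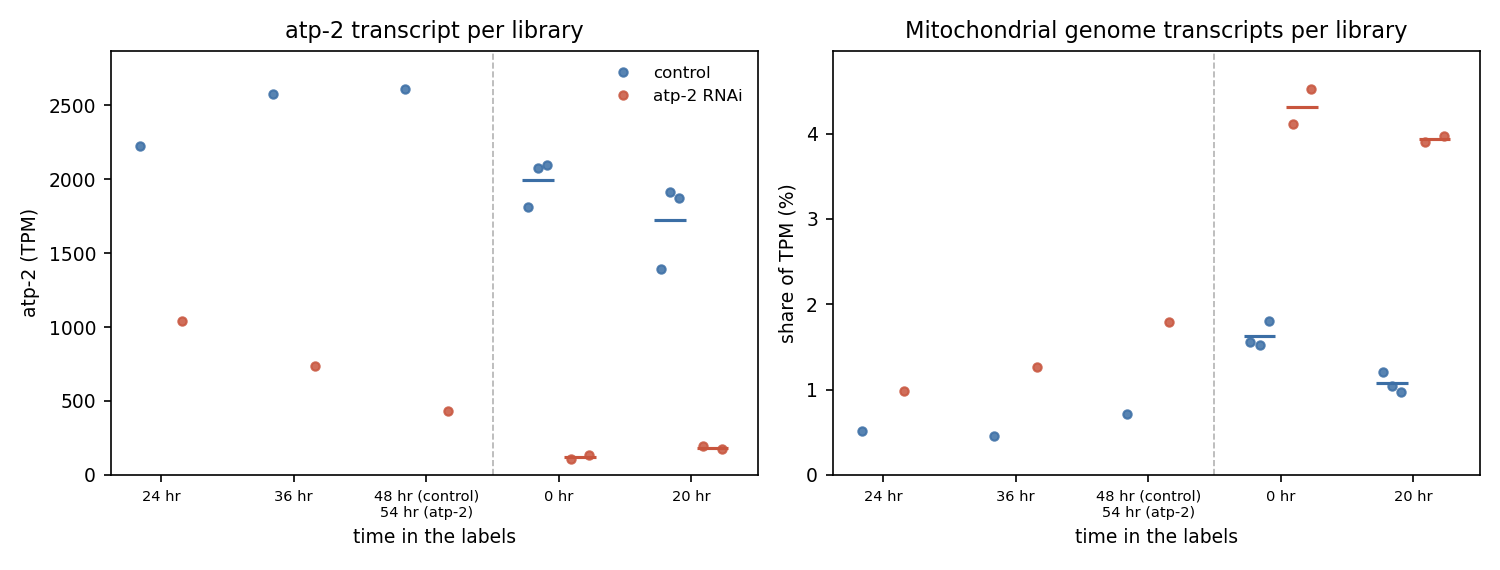
The left panel plots the atp-2 level in TPM and the right panel the share of all TPM from all genes of the mitochondrial genome. Each dot is 1 library (blue control, red atp-2 RNAi) and each bar a group mean where there are replicates. The dashed line separates the unreplicated times from 0 hr and 20 hr. The 7 atp-2 RNAi libraries lie between 110 and 1043 TPM of atp-2, all below the 9 control libraries (1389 to 2607 TPM), and at 0 hr and 20 hr their mitochondrial share lies between 3.90% and 4.52% against 0.97% to 1.80% in the controls.

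The first replicated comparison asked how expression after atp-2 RNAi differed from control at 0 hr. Across genes the atp-2 RNAi libraries of 0 hr correlated at 0.918 to 0.935 with the controls of 24 hr and 36 hr. With the controls of 0 hr they correlated at 0.533 to 0.608. The changes may thus hold a difference in stage as well as an effect of treatment. Yolk, egg and some collagen genes fell furthest. The yolk protein gene vit-6 (WBGene00006930, chromosome IV, 8261134 to 8266462) fell from 2185 ± 547 TPM (n = 3) to 0.338 ± 0.0744 TPM (n = 2), a log2 change of -10.65 (SE 0.20, limma adjusted p = 5.4e-08), and vit-2 from 1941 ± 426 to 0.335 ± 0.201 TPM. Another yolk protein gene, vit-5, was listed at 0 in both atp-2 RNAi libraries against 1476 ± 279 TPM in controls. The collagen gene col-119 (WBGene00000693, chromosome IV, 8978823 to 8979812) had the largest fall of all, from 4155 ± 373 to 0.536 ± 0.622 TPM (-11.46, SE 0.24, limma adjusted p = 7.16e-08). Other collagen genes, col-124 (-10.69), col-20 (-10.56), col-8 (-10.50) and col-19 (-10.17), fell by nearly as much.

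Every tested gene of the vitellogenin list fell (6 of 6, and 6 adjusted over the list alone; median -10.23, which includes vit-5). Oocyte, eggshell and maternal genes fell in 28 of 29 cases (28 adjusted over the list alone), with a median of -7.03, led by the eggshell genes perm-2 (-10.07) and perm-4 (-9.37). All 35 germline proliferation and meiosis genes fell (35 adjusted over the list alone; median -3.54), among them gld-1, a regulator of germ cell translation, from 451 ± 49.9 to 6.52 ± 0.535 TPM (-5.91, SE 0.14, limma adjusted p = 1.44e-07). Major sperm protein genes fell in 29 of 29 cases (29 adjusted over the list alone; median -5.64), with msp-59 going from 125 ± 52.9 to 0.308 ± 0.243 TPM. Among the other sperm genes 26 of 28 fell and 1 rose (26 and 1 adjusted over the list alone; median -4.39), led by ssq-1 (-6.36) and ssq-2 (-6.33). The set test camera put these 5 lists below the other genes with adjusted p of 5.8e-05, 1.01e-12, 4.96e-12, 1.46e-09 and 6.64e-07 in that order. With an estimated correlation between genes the adjusted p = 0.601 for the first 4 and adjusted p = 0.608 for the other sperm genes, so these calls rest on the preset form of camera. The estimated form also uses the few residual degrees of freedom of the fit. Here and for the lists below, its adjusted p therefore does not measure the correlation between genes alone. Major sperm protein, vitellogenin and collagen genes have near-identical copies, so the values of single members are uncertain.

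Genes of cuticle building rose. The collagen gene col-41 (WBGene00000618, chromosome X, 15175035 to 15176481) was at 1180 ± 577 TPM after atp-2 RNAi and 0.0959 ± 0.0531 TPM in controls (9.98, SE 0.29, limma adjusted p = 2.38e-07). Body shape collagens behaved alike, with dpy-4 at 2546 ± 1077 against 8.27 ± 7.25 TPM (8.42), rol-6 at 8.40, sqt-1 at 8.13 and sqt-3 at 8.02, as did the collagen gene col-17 (9.33), the cuticlin gene cut-2 (8.12) and ZK180.5 (8.36). In the molting and cuticle list 32 of 33 genes rose (32 adjusted over the list alone; median 5.13, camera adjusted p = 4.72e-09). These included cut-2 and the lipocalin-related gene lpr-3 (7.94). The adjusted p = 0.601 with an estimated correlation. Collagens went both ways, with 93 of 161 higher, 40 lower and 28 not past the threshold (93 and 40 adjusted over the list alone; median 1.65, mean 1.13, camera adjusted p = 0.028, adjusted p = 0.767 with an estimated correlation). The camera call of the collagens ended without control replicate 1.

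Transcripts encoded by the mitochondrial genome rose as a group at 0 hr. All 12 of its protein-coding genes were higher (12 adjusted over the list alone; median 1.5, camera adjusted p = 0.000542, adjusted p = 0.601 with an estimated correlation). The gene ndfl-4, for a subunit of NADH dehydrogenase (mitochondrial DNA, 549 to 783), was at 48.4 ± 8.96 against 2.02 ± 0.404 TPM (4.03) and nduo-6 at 432 ± 178 against 84.0 ± 20.2 TPM (2.31). Nuclear genes of the electron transport chain showed no such common rise, since 10 of 34 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.17, mean -0.06, camera adjusted p = 0.359). Of the 15 other nuclear ATP synthase genes, 5 rose and 3 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.643), and their median of 0.13 became -0.01 after all libraries were shifted to a common median. The largest changes in both lists were falls, of ucr-2.3 (-4.61), nduf-2.2 (-3.91), asb-1 (-3.35) and asg-1 (-1.78). In the mitochondrial unfolded protein response list 15 of 24 genes rose and 1 fell (15 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 0.0113, adjusted p = 0.601 with an estimated correlation). Its leading members were the tubulin gene tbb-6 (WBGene00006539, chromosome V, 12261804 to 12263368), at 436 ± 195 against 3.58 ± 0.602 TPM (6.51, SE 0.27, limma adjusted p = 1.05e-06), and the cytochrome P450 gene cyp-14A4 (6.48). The chaperone hsp-6, the usual reporter gene of this response and named here after its values were seen, was at 736 ± 60.3 against 643 ± 42 TPM (0.19, limma adjusted p = 0.165), and hsp-60, named likewise, fell by 0.84 (limma adjusted p = 2.09e-04).

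Most detoxification lists and some defence lists were higher at 0 hr, while lysozyme, saposin-like and lectin genes went both ways (54 higher, 40 lower and 22 not past the threshold, the same adjusted over the list alone; median 0.16, camera adjusted p = 0.528). In these libraries the germline and oocyte lists lay at -3.54 and -7.03 and the intestine and body wall muscle lists at 0.32 and 1.05. Cytochrome P450 genes rose in 43 of 57 cases and fell in 7 (43 and 7 adjusted over the list alone; median 1.45, camera adjusted p = 7.83e-05, adjusted p = 0.601 with an estimated correlation). Glutathione S-transferase genes rose in 26 of 38 cases and fell in 3 (26 and 3 adjusted over the list alone; camera adjusted p = 0.00366, adjusted p = 0.601 with an estimated correlation). The largest rise was in gst-14 (5.0). UDP-glucuronosyltransferase genes rose in 35 of 56 cases and fell in 8 (35 and 7 adjusted over the list alone; camera adjusted p = 0.00658, adjusted p = 0.645 with an estimated correlation). Of these ugt-19 was at 370 ± 70.1 against 13.3 ± 6.42 TPM (4.78). Of the ABC transporters 22 of 38 rose and 10 fell (24 and 10 adjusted over the list alone). The list did not pass (camera adjusted p = 0.121), although pgp-9 rose from 7.02 ± 4.48 to 283 ± 1.68 TPM (5.29). The hypoxia and sulfide list rose in 12 of 14 genes (12 adjusted over the list alone; camera adjusted p = 0.00793, adjusted p = 0.601 with an estimated correlation). Its members cysl-2 (2.42) and nhr-57 (2.45) were higher. Epidermal antimicrobial peptide genes rose in 16 of 19 cases (16 adjusted over the list alone; median 2.86, camera adjusted p = 0.00022, adjusted p = 0.601 with an estimated correlation). The gene nlp-34 was at 109 ± 52.4 against 1.47 ± 0.396 TPM (5.4). Its relative cnc-6 was listed at 0 in the 3 controls against 42.9 ± 26.3 TPM after atp-2 RNAi. The intracellular pathogen response list rose in 21 of 23 genes (21 adjusted over the list alone; median 2.29, camera adjusted p = 0.000542, adjusted p = 0.601 with an estimated correlation). Among these were pals-39 (3.63) and pals-6 (3.52).

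Neuronal genes, the object of the study, were mostly higher in whole worms at 0 hr, in the same libraries in which the germline and oocyte lists had medians of -3.54 and -7.03. FMRFamide-like peptide genes, which encode neuropeptides, rose in 23 of 30 cases and fell in 3 (23 and 3 adjusted over the list alone; median 1.55, camera adjusted p = 0.000529, adjusted p = 0.608 with an estimated correlation). The gene flp-15 (WBGene00001458, chromosome III, 13663400 to 13667839) was at 180 ± 40.9 TPM (n = 2) against 9.65 ± 5.11 TPM (n = 3), a log2 change of 4.19 (SE 0.38, limma adjusted p = 3.08e-05), followed by flp-34 (3.47), flp-16 (3.33) and flp-20 (3.33). Other neuropeptide-like genes rose in 42 of 55 cases and fell in 9 (42 and 9 adjusted over the list alone; median 1.76, camera adjusted p = 0.000114, adjusted p = 0.611 with an estimated correlation). Among them nlp-12 was at 408 ± 108 against 16.9 ± 9.32 TPM (4.61) and nlp-20 at 703 ± 82.9 against 43.3 ± 26.6 TPM (4.15). Genes of neuropeptide processing and dense-core vesicles all rose (14 of 14, and 14 adjusted over the list alone; median 1.77, camera adjusted p = 0.000236, adjusted p = 0.601 with an estimated correlation). They were led by ida-1 (3.72) and the prohormone convertase gene egl-3 (2.73). Synaptic vesicle genes rose in 28 of 31 cases and fell in 1 (28 and 1 adjusted over the list alone; median 1.53, camera adjusted p = 3.72e-05, adjusted p = 0.601 with an estimated correlation). The active zone genes cla-1 and unc-10 had changes of 2.71 and 2.37.

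The transmitter systems differed in how many members passed at 0 hr. Acetylcholine and GABA genes rose in 24 of 26 cases and none fell (24 adjusted over the list alone; median 1.29, camera adjusted p = 0.000146, adjusted p = 0.608 with an estimated correlation). The GABA receptor gene unc-49 was at 68.3 ± 0.281 against 8.19 ± 3.21 TPM (2.97) and exp-1 at 2.34. Serotonin genes rose in 5 of 13 cases, led by the receptor gene ser-4 (1.89) and lgc-50 (1.57), and the list did not pass (5 adjusted over the list alone; camera adjusted p = 0.267). Glutamate genes rose in 9 of 19 cases and fell in 4 (9 and 4 adjusted over the list alone; camera adjusted p = 0.205). The vesicular glutamate transporter gene eat-4 was higher (1.97) and the ubiquitin protease gene usp-46 lower (-1.95). Among the dopamine, octopamine and tyramine genes 8 of 15 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.267). The largest changes there were falls of tdc-1, the tyrosine decarboxylase gene that is also expressed in the gonad sheath, from 87.2 ± 16.8 to 9.78 ± 1.25 TPM (-3.02), and of tbh-1 (-4.36, SE 1.36, limma adjusted p = 0.0177), whose atp-2 RNAi value of 27.3 ± 38.6 TPM has an SD above its mean. The call of tbh-1 ended with no filter on low values. Learning and memory genes rose in 35 of 42 cases and fell in 3 (35 and 3 adjusted over the list alone; median 1.27, camera adjusted p = 0.000185, adjusted p = 0.601 with an estimated correlation). Another list also holds 12 of the 49 genes of this list. The calcium/calmodulin kinase gene cmk-1 was at 24.2 ± 1.66 against 1.80 ± 0.634 TPM (3.19), gsa-1 at 2.68 and unc-7 at 2.4, while the ubiquitin ligase gene fsn-1 fell to 8.36 ± 1.02 TPM (-3.14). Chemoreceptor genes rose in 29 of the 40 tested (29 adjusted over the list alone) and sensory transduction genes in 27 of 32 (27 adjusted over the list alone), with camera adjusted p of 0.000542 and 0.00014 and, for both, adjusted p = 0.601 with an estimated correlation. These lists hold 1313 and 72 genes, most of them below the mean of 1 TPM needed for a test. A gene high in 1 group alone can reach that mean, so the counts do not describe the whole families.

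In all, 6165 genes were higher and 5576 lower at 0 hr among 14094 tested, which is 83.3% of them. Of these calls, 4676 and 4108 had a fitted change of at least 2-fold, with no test against 2-fold, and 782 and 942 had one of at least 8-fold. The median of all tested genes lay 0.15 higher on the log2 scale in atp-2 RNAi libraries than in controls, so a change smaller than that depends on the scaling, and after a shift to a common median the counts were 5711 and 5856. In simulated data on the same genes, with only 100 genes changed 2-fold and 100 changed 4-fold, 68% and 99% of these were recovered. With 83.3% of genes called here the adjusted threshold differs, so these shares do not carry over.

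**Figure D2:**
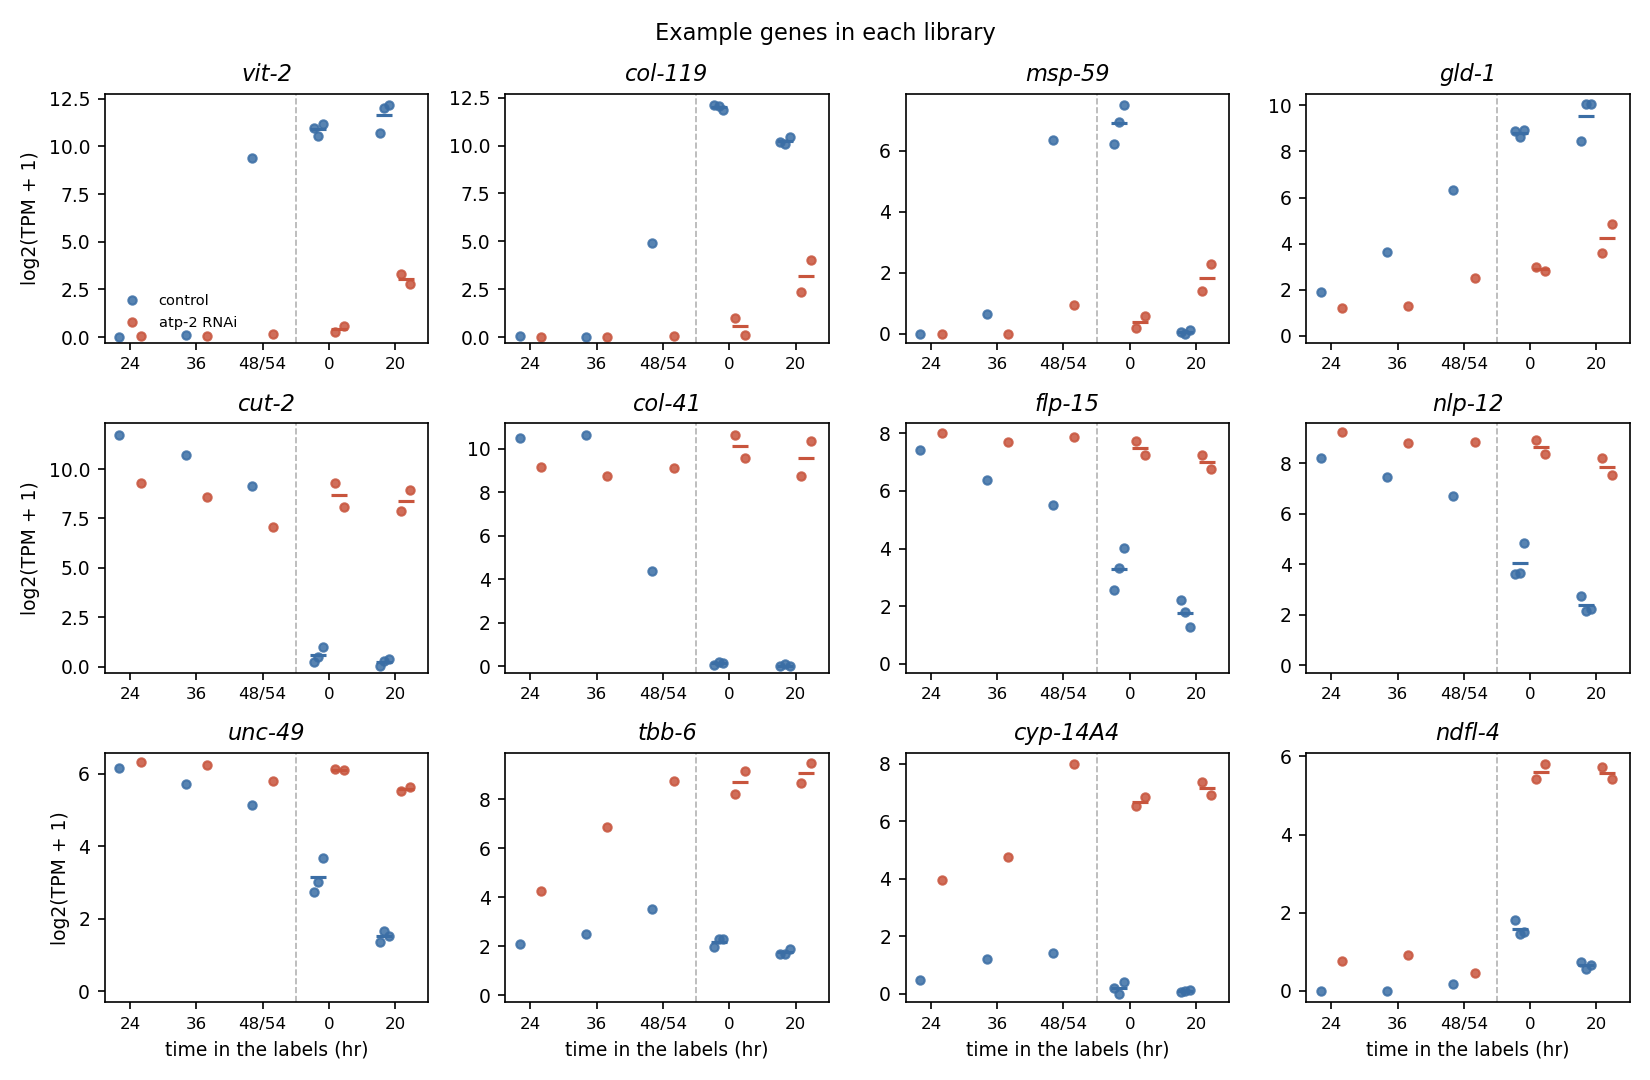
Each panel plots 1 gene as log2(TPM + 1) against the time in the labels in hours, each dot being 1 library (blue control, red atp-2 RNAi) and each bar a group mean where there are replicates; at 48/54 the control is 48 hr and the atp-2 RNAi library 54 hr. At 0 hr vit-2, col-119, msp-59 and gld-1 are lower and cut-2, col-41, flp-15, nlp-12, unc-49, tbb-6, cyp-14A4 and ndfl-4 higher in both atp-2 RNAi libraries than in the 3 controls.

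The second replicated comparison repeated the contrast at 20 hr, where yolk genes had the lowest changes and cuticle collagens the highest. The atp-2 RNAi libraries of 20 hr correlated at 0.886 to 0.927 with the controls of 24 hr and 36 hr. With the controls of 20 hr they correlated at 0.555 to 0.572, so a difference in stage may be part of these changes too. The yolk protein gene vit-6 was at 4.57 ± 2.17 TPM (n = 2) against 3534 ± 1609 TPM (n = 3), a log2 change of -9.23 (SE 0.45, limma adjusted p = 1.53e-06). Larger falls were fitted for vit-5, at 0.0474 ± 0.0408 against 3898 ± 2184 TPM (-11.64), vit-3 (-11.10), vit-4 (-11.08) and vit-1 (-10.07), with vit-3 and vit-4 being near-identical copies. Next came the neighbouring genes ule-5 (-9.44) and Y62H9A.5 (-9.38) and the eggshell gene perm-2 (-9.25). The largest rise was in dpy-4 (WBGene00001066, chromosome IV, 14985543 to 14986784), at 1843 ± 1425 against 0.244 ± 0.193 TPM (10.29, SE 0.46, limma adjusted p = 1.16e-06), followed by dpy-5 (10.25), col-17 (10.23), col-125 (3269 ± 1310 against 1.72 ± 0.64 TPM), dpy-13 (10.07), F41F3.3 (10.02), col-73 (9.57) and col-41 (9.53).

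Germline and egg genes fell at 20 hr as they had at 0 hr. All 6 vitellogenins (median -10.57), all 29 oocyte genes (median -7.07) and all 35 germline genes (median -3.82) were lower, with the same counts adjusted over the list alone. Their camera adjusted p were 0.00241, 1.03e-10 and 2.47e-09, and for each the adjusted p = 0.528 with an estimated correlation. The chromatin gene nasp-2 fell to 13.9 ± 5.37 from 1344 ± 106 TPM (-6.54, SE 0.22, limma adjusted p = 4.36e-07) and the germ granule gene deps-1 fell by 5.58. Sperm genes did not follow. Only 3 major sperm protein genes reached a mean of 1 TPM at 20 hr, and 2 of them were higher (2 adjusted over the list alone), with msp-59 at 2.73 ± 1.55 against 0.0442 ± 0.0425 TPM (1.77) and msp-57 at 1.61. Of the 9 other sperm genes tested, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.854), and their median of 0.11 became -0.01 after a median shift and -0.97 after quantile normalization. The molting and cuticle list was higher in 32 of 33 genes (32 adjusted over the list alone; median 3.81, camera adjusted p = 3.54e-05, adjusted p = 0.627 with an estimated correlation). Collagens were higher in 115 of 149 cases and lower in 25 (115 and 25 adjusted over the list alone; median 3.63, camera adjusted p = 1.23e-06, adjusted p = 0.601 with an estimated correlation). Body wall muscle genes were higher in 23 of 24 cases (23 adjusted over the list alone; median 2.74, camera adjusted p = 0.000148, adjusted p = 0.528 with an estimated correlation). The myosin heavy chain gene unc-54 was at 650 ± 57.4 against 21.3 ± 10.3 TPM (5.0) and myo-3 at 4.7.

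Mitochondrial genome transcripts were again higher, in 12 of 12 genes (12 adjusted over the list alone; median 2.17, camera adjusted p = 0.000743, adjusted p = 0.528 with an estimated correlation). The gene ndfl-4 was at 47 ± 6.93 against 0.570 ± 0.0953 TPM (4.93) and nduo-6 at 3.53. Nuclear electron transport chain genes rose in 24 of 34 cases and fell in 3 (24 and 3 adjusted over the list alone; median 0.61, camera adjusted p = 0.0269, adjusted p = 0.714 with an estimated correlation). That call ended after a median shift, with the replicate block, and without control replicate 2 or control replicate 3. The largest changes of that list were falls, of ucr-2.3 (-4.29) and nduf-2.2 (-3.72). Other nuclear ATP synthase genes rose in 12 of 15 cases and fell in 2 (12 and 2 adjusted over the list alone), without passing as a list (camera adjusted p = 0.12). Only 7 were higher after a median shift and 8 after quantile normalization. Here asb-1 fell (-3.63) and mai-1, a homologue of the inhibitor of the synthase, rose from 8.21 ± 1.41 to 62.8 ± 14.9 TPM (2.78). In the mitochondrial unfolded protein response list 10 of 24 genes rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0624), and quantile normalization gave 17 and 1, with the median going from 0.30 to 0.82. Here tbb-6 was at 569 ± 226 against 2.37 ± 0.275 TPM (7.35) and cyp-14A4 at 7.04, while hsp-6 was at 978 ± 150 against 764 ± 68.9 TPM (0.35, limma adjusted p = 0.0516).

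Detoxification lists rose together at 20 hr, in libraries in which the germline and oocyte lists lay at -3.82 and -7.07 and the intestine and body wall muscle lists at 1.56 and 2.74. Cytochrome P450 genes were higher in 44 of 54 cases (44 adjusted over the list alone; camera adjusted p = 0.000212, adjusted p = 0.559 with an estimated correlation). Among them cyp-33C8 was at 803 ± 96.6 against 5.87 ± 3.35 TPM (6.98). Glutathione S-transferases were higher in 30 of 34 cases and UDP-glucuronosyltransferases in 44 of 55 (30 and 44 adjusted over the list alone), with camera adjusted p of 0.000239 and 0.000212 and, for both, adjusted p = 0.528 with an estimated correlation. The UDP-glucuronosyltransferase gene ugt-19 rose from 7.35 ± 1.56 to 543 ± 33.2 TPM (6.04) and gst-14 by 5.97. ABC transporters rose in 24 of 34 cases (24 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.559 with an estimated correlation). Here pgp-9 rose (5.91) and mrp-4 fell (-3.90). Epidermal antimicrobial peptide genes rose in 18 of 19 cases (18 adjusted over the list alone; median 3.85, camera adjusted p = 0.000103, adjusted p = 0.528 with an estimated correlation). They were led by nlp-34 (6.14) and nlp-30 (5.11).

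Neuropeptide genes had larger median differences at 20 hr than most other lists, again in libraries whose germline list lay at -3.82. FMRFamide-like peptide genes were higher in 26 of 29 cases (26 adjusted over the list alone; median 2.63, camera adjusted p = 3.17e-05, adjusted p = 0.528 with an estimated correlation). Other neuropeptide-like genes were higher in 46 of 51 (46 adjusted over the list alone; median 3.04, camera adjusted p = 6.5e-07, adjusted p = 0.528 with an estimated correlation). The gene flp-15 was at 130 ± 32.3 against 2.53 ± 1.1 TPM (5.24, SE 0.29, limma adjusted p = 2.5e-06) and nlp-20 at 445 ± 53.8 against 7.16 ± 3.09 TPM (5.85, SE 0.32, limma adjusted p = 2.3e-06). Next came nlp-12 (5.50), nlp-43 (5.17), nlp-13 (4.98), flp-20 (4.92), flp-16 (4.81) and flp-5 (4.56). Dense-core vesicle genes rose in 14 of 14 cases (14 adjusted over the list alone; median 2.44, camera adjusted p = 0.000622, adjusted p = 0.528 with an estimated correlation). Their leading members were ida-1 at 5.19 and the amidating enzyme gene pghm-1 at 4.42. Synaptic vesicle genes rose in 23 of 31 cases and fell in 2 (23 and 2 adjusted over the list alone; median 1.83, camera adjusted p = 0.00203, adjusted p = 0.559 with an estimated correlation). Among these were ric-4 (3.20) and unc-13 (2.86). Acetylcholine and GABA genes rose in 22 of 24 cases (22 adjusted over the list alone; median 1.90, camera adjusted p = 6.13e-05, adjusted p = 0.528 with an estimated correlation). The gene unc-49 was at 46.7 ± 2.61 against 1.87 ± 0.315 TPM (4.06), snf-11 at 3.31, ace-2 at 3.29 and gbb-2 at 3.10. Under quantile normalization the median of the synaptic vesicle genes was 1.12 and that of the acetylcholine and GABA genes 0.79, with 19 higher and 2 lower.

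Glutamate genes rose in 13 of 17 cases (13 adjusted over the list alone) and serotonin genes in 8 of 11 (8 adjusted over the list alone) without passing as lists (camera adjusted p = 0.0521 and 0.166). Quantile normalization left 5 glutamate genes higher and 4 lower, with the median going from 1.31 to 0.29, and 6 serotonin genes higher and 3 lower. Single members were eat-4 at 2.25, the serotonin-gated channel gene lgc-50 at 2.33, cat-4 at 2.22, ser-4 at 2.22 and usp-46 at -2.94. Among the 10 dopamine, octopamine and tyramine genes tested, 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.657). Their median was 0.63 and their mean -0.27, and quantile normalization turned the median to -0.52. The dopamine receptor genes dop-1 (2.05) and dop-3 (1.99) rose, while tdc-1 (-4.16) and tbh-1 (-5.56, SE 1.29) fell. Learning and memory genes rose in 30 of 42 cases and fell in 6 (30 and 6 adjusted over the list alone; median 1.79, camera adjusted p = 0.00388, adjusted p = 0.528 with an estimated correlation). Among them were cmk-1 at 3.37, gsa-1 at 3.31, the protein kinase A gene kin-1 at 141 ± 1.34 against 15.1 ± 5.95 TPM (3.22) and fsn-1 at -3.84.

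At 20 hr 6158 genes were higher and 5253 lower among 12916 tested (88.3%). Of these, 5311 and 4250 had a fitted change of at least 2-fold, with no test against 2-fold. The median of all tested genes lay 0.12 higher in atp-2 RNAi libraries. The median fitted change over tested genes was 0.31, so a list median near that size, such as 0.30 for the mitochondrial unfolded protein response, matches the typical tested gene. A median shift gave 5956 and 5463, and quantile normalization, which forces libraries to the same distribution, turned the sign of 683 called genes. The count of higher genes was 9342 with no filter on low values and 3925 with a filter at a mean of 5 TPM.

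**Figure D3:**
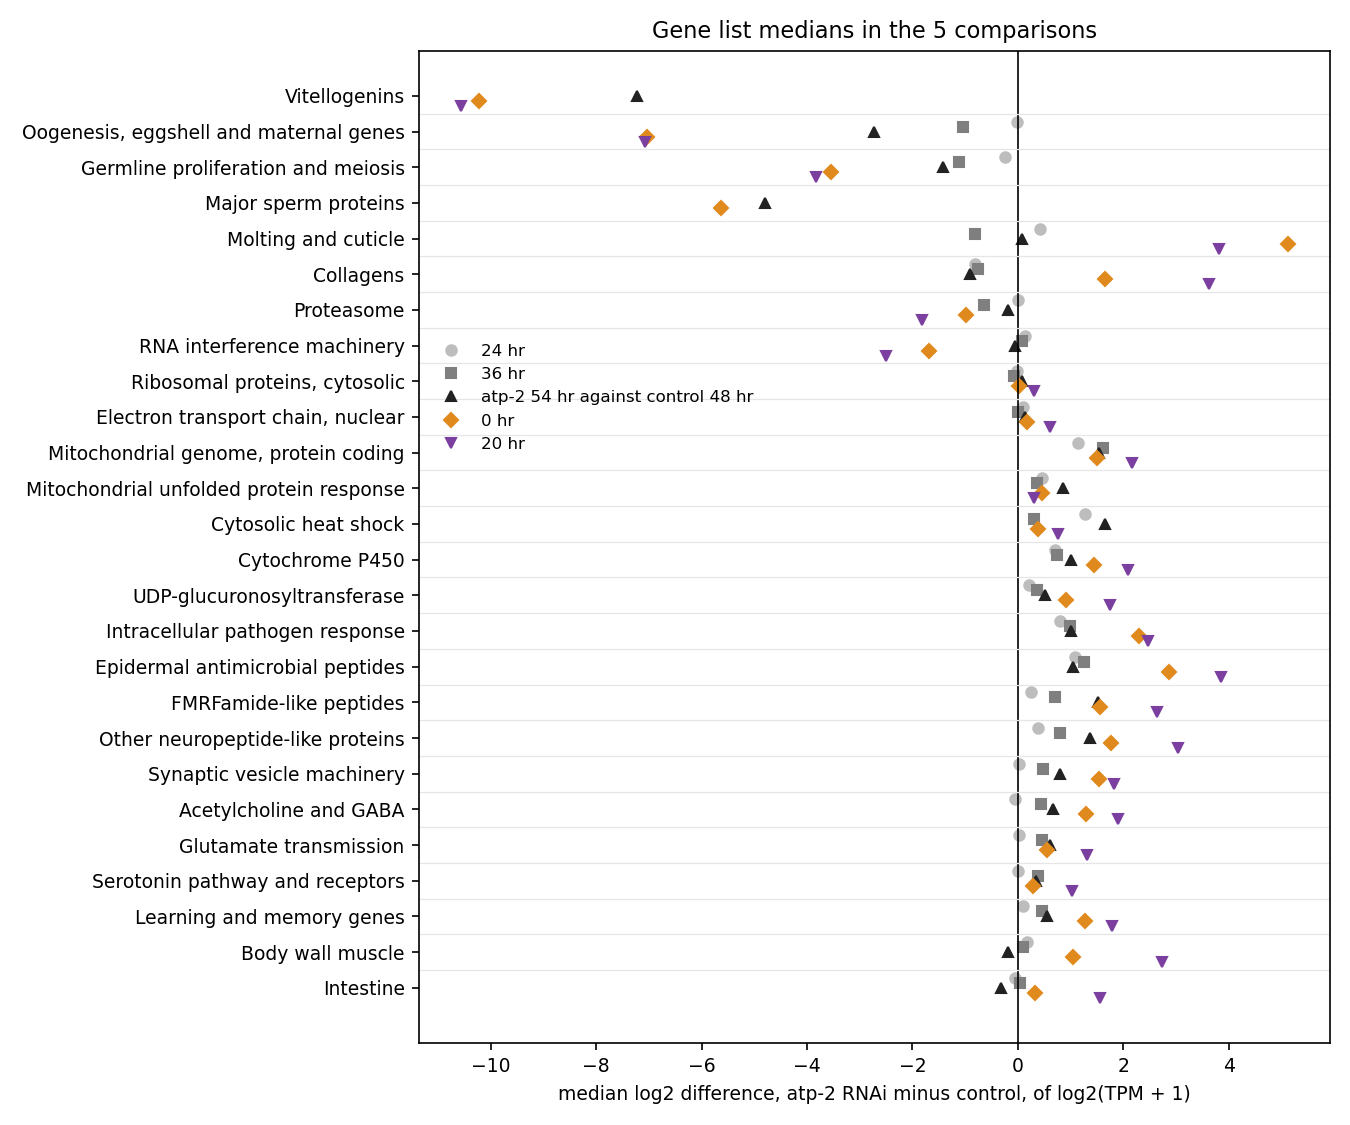
Each symbol is the median over a gene list of the difference in log2(TPM + 1) between atp-2 RNAi and control, in the 3 unreplicated pairs (greys and black) and at 0 hr (orange) and 20 hr (purple); major sperm protein genes are left out at 20 hr, where only 3 were tested. Yolk and oocyte medians are the lowest at 0 hr and 20 hr, the mitochondrial genome median lies between 1.14 and 2.17 in all 5 comparisons, and the medians of ribosomal proteins (at both 0 hr and 20 hr) change sign under another scaling.

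The changes at 0 hr and 20 hr were compared gene by gene. Genes of yolk, oocytes, cuticle building, neuropeptides and detoxification moved the same way at both times, and sperm genes and a part of the collagens did not. The tables of the 2 times share no control library. Among 12720 genes tested at both, 5177 were higher at both times (2770 with independent lists) and 4370 lower at both (1928 with independent lists). By contrast 44 were higher at 0 hr and lower at 20 hr and 154 the reverse (4623 opposite calls with independent lists). Across genes, which are not independent replicates, the changes correlated with Pearson's r of 0.91 and Spearman's rho of 0.92. The test of the difference between both changes called 2886 genes with a more positive and 2991 with a more negative change at 20 hr among 13679 (2420 and 4207 after a median shift). This lower count fell to 1875 without control 0 hr replicate 2, 1380 without atp-2 RNAi 0 hr replicate 2, 1915 without atp-2 RNAi 0 hr replicate 3, 1964 without control 20 hr replicate 2 and 1531 without atp-2 RNAi 20 hr replicate 2. The collagen gene col-81 had the largest difference, with a change of -9.83 at 0 hr and 1.0 at 20 hr (difference 10.84, SE 0.79, limma adjusted p = 1.44e-05), and pud-1.2 the most negative, with 0.73 at 0 hr and -3.02 at 20 hr (difference -3.75, SE 0.49, limma adjusted p = 0.000438). For major sperm protein genes, 28 of 28 had a more positive change at 20 hr (28 adjusted over the list alone; median 6.65, camera adjusted p = 4.92e-25, adjusted p = 0.769 with an estimated correlation).

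**Figure D4:**
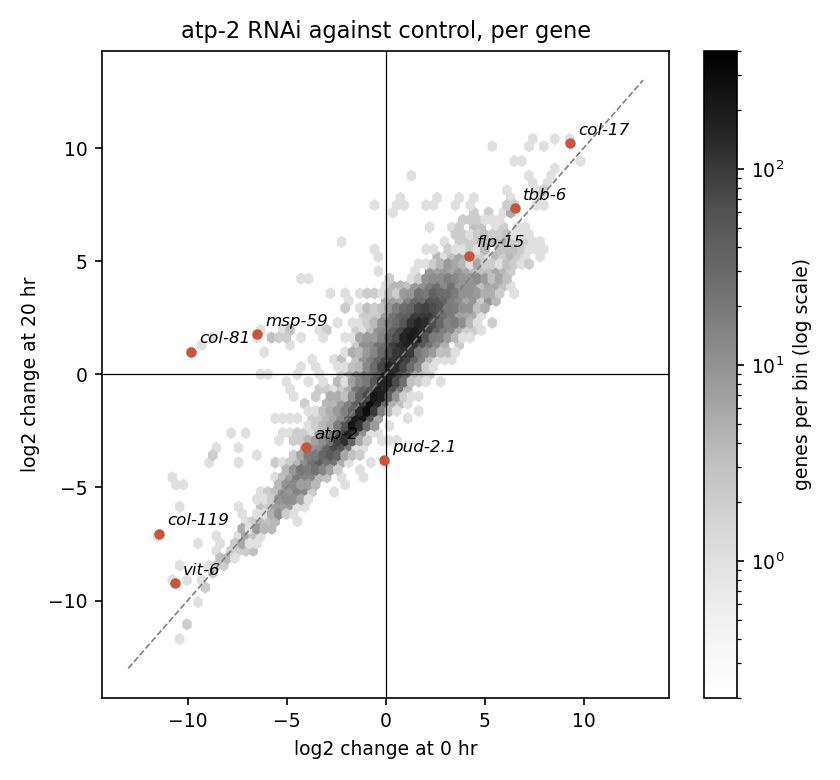
Each grey bin counts the genes with a given log2 change at 0 hr (horizontal axis) and 20 hr (vertical axis), darker bins holding more genes on a log scale, with the dashed line marking equal changes and the red dots marking named genes. Most genes lie near the dashed line (r = 0.91), vit-6 (-10.65 and -9.23) and col-17 (9.33 and 10.23) lie at its ends, and col-81, msp-59 and pud-2.1 lie far from it.

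The unreplicated pairs followed the worms at 24 hr, 36 hr and 54 hr against 48 hr, with 1 library per group, so none of the differences that follow has a replicate check and none has a p-value. At 24 hr the clearest differences were in stress and cuticle genes. The small heat shock genes hsp-16.2 (125 against 14.4 TPM, log2 ratio 3.03) and hsp-16.41 (2.83) were higher, and the cytosolic heat shock list had a median of 1.28, above the central 95% of random lists matched on expression (-0.07 to 0.34), with 11 of 19 members at least 2-fold higher. Mitochondrial genome genes had a median of 1.14 (random lists -0.13 to 0.42), with nduo-2 at 18.8 against 2.09 TPM, and cytochrome P450 genes 0.70 (-0.02 to 0.27), with cyp-14A4 at 14.5 against 0.391 TPM. Collagens had a median of -0.82 (0.04 to 0.20). At least 2-fold lower were 59 of 126 and higher 24, including col-133 at 11.8 against 381 TPM (-4.90) and col-162 (-4.17). In contrast fbn-1, a fibrillin-like matrix gene, was at 155 against 23.1 TPM (2.70). Of the neuronal lists, neuropeptide-like genes outside the epidermal cluster had a median of 0.38 (-0.00 to 0.26) and neuropeptide processing and dense-core vesicle genes 0.39 (-0.10 to 0.35), both above their range. Synaptic vesicle genes at 0.02 (-0.03 to 0.28) and learning and memory genes at 0.09 (0.00 to 0.27) lay within it. The germline list was at -0.24 (-0.08 to 0.32). Among single genes the highest ratios were those of F22B3.7 (4.68), F12A10.7 (3.73), fipr-24 (3.71), fipr-23 (3.62), col-176 (3.58) and col-98 (3.56). Among the lowest, beside col-133 and col-162, were lips-6 (-4.26), C06E8.5 (-3.90), dct-5 (-3.82) and F35B3.4 (-3.79). Counting all genes with a mean of at least 1 TPM, 804 of 12548 were at least 2-fold higher and 515 lower (660 and 601 after a median shift).

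At 36 hr germline and neuropeptide genes had also moved apart. Germline genes had a median log2 ratio of -1.12 (random lists -0.03 to 0.40), with 19 of 35 at least 2-fold lower, among them pgl-1, a germ granule gene, at 1.88 against 18.3 TPM and glh-1 at 8.17 against 57.3 TPM. Molting genes were at -0.82 (-0.07 to 0.32), with the hedgehog-related gene wrt-4 at 3.46 against 34.1 TPM. In the other pairs the molting list did not fall. It was at 0.42 at 24 hr (-0.02 to 0.28) and at 0.08 for 54 hr against 48 hr (-0.15 to 0.41). FMRFamide-like peptide genes were at 0.71 (-0.08 to 0.35), with flp-24 at 109 against 41.7 TPM, and other neuropeptide-like genes at 0.79 (-0.02 to 0.29), with nlp-35 at a log2 ratio of 1.87. Other neuronal lists also lay above their ranges, such as synaptic vesicle genes at 0.47 (-0.06 to 0.32) and learning and memory genes at 0.46 (-0.05 to 0.3). Serotonin, glutamate, insulin-like peptide and acetylcholine and GABA genes lay within theirs. Mitochondrial genome genes were at 1.61 (-0.28 to 0.33), and all 11 were at least 2-fold higher, led by nduo-2 at 73.0 against 0.854 TPM (5.32). Among single genes, tbb-6 was at 118 against 4.67 TPM (4.39), F22B3.7 at 26.8 against 0.0903 TPM (4.67), gst-14 at 4.13, F54B8.4 at 4.17 and the mitochondrial tRNA gene MTCE.22 at 4.44. Lower were the fatty acid desaturase gene fat-7 at 0.316 against 19.8 TPM (-3.98), lips-6 at -3.32, col-133 at -3.32 and acox-1.2 at -3.15. The short non-coding genes T04C12.23 and F25H2.16 were listed at 0 in the atp-2 RNAi library against 83.3 and 34.8 TPM in the control. In total 940 of 12416 genes were at least 2-fold higher and 690 lower (673 and 892 after a median shift).

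The pair of atp-2 RNAi at 54 hr and control at 48 hr differs in treatment and in 6 hr of time, which cannot be separated. Although taken later, the atp-2 RNAi library correlated at 0.925 and 0.933 with the controls of 24 hr and 36 hr and at 0.846 with that of 48 hr. A younger stage of the treated worms therefore cannot be separated from treatment either. Yolk, egg and sperm genes were lower, with vit-6 at 0.115 against 785 TPM (-9.46) and vit-2 at -9.20. List medians were, for vitellogenins, -7.22 (random lists -0.60 to 0.79), for the oocyte list -2.73 (-0.18 to 0.60), for the germline list -1.42 (-0.11 to 0.57) and for major sperm proteins -4.80 (-0.08 to 0.53). All 28 major sperm protein genes were at least 2-fold lower. Collagens went both ways, with 81 of 165 at least 2-fold lower and 40 higher, and a median of -0.91 (-0.07 to 0.18). Among the lowest were col-63 at 0.313 against 1343 TPM, col-138 (-9.79), rol-1 (-9.47) and col-175 (-9.36). Cytochrome P450 genes had a median of 1.01 (-0.07 to 0.45), with 30 of 60 at least 2-fold higher and 9 lower. UDP-glucuronosyltransferases also lay above their range (0.51, -0.08 to 0.44). Glutathione S-transferases (0.49, -0.17 to 0.52) and ABC transporters (0.25, -0.12 to 0.51) lay within theirs. Among the highest single genes were cyp-13A8 at 256 against 1.12 TPM (6.92) and cyp-14A4 at 250 against 1.67 TPM (6.55). Next to these 2 genes stood F22B3.7 (6.47), the non-coding gene tts-1 at 2469 against 46.5 TPM (5.70) and T16G1.6 (5.59), while C04C3.14 was at 57.7 TPM and listed at 0 in the control. FMRFamide-like peptide genes had a median of 1.52 (-0.15 to 0.55), with flp-15 at 234 against 44.5 TPM, and the learning and memory list 0.56 (-0.11 to 0.46), with casy-1 at 62.7 against 18.1 TPM and tir-1 at 80.8 against 21 TPM. In total 2403 of 13473 genes were at least 2-fold higher and 2003 lower (1772 and 2377 after a median shift).

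Some genes differed the same way at every time. Among 11699 genes kept in the 3 unreplicated pairs, 290 were at least 2-fold higher in all of them (9.8 with independent lists), among them F22B3.7, cyp-14A4, clec-17, nduo-2, gst-14, ugt-19, tbb-6 and mtl-1. Of 289 of these tested at 0 hr, 253 were called higher and 17 lower, and of 285 tested at 20 hr, 264 were higher and 9 lower. The 141 genes at least 2-fold lower in all of the pairs (1.7 with independent lists) mostly went the other way at 0 hr and 20 hr. Of 139 tested at 0 hr, 106 were called higher and 18 lower, and of 136 tested at 20 hr, 114 were higher and 13 lower. The cuticlin gene cut-2 was among them, with log2 ratios of -2.43, -2.14 and -2.1 in the pairs and changes of 8.12 at 0 hr and 8.14 at 20 hr. For this gene the sign turned with the control level. Controls stood at 3412, 1669 and 570 TPM in the pairs and between 0.036 and 1.0 TPM at 0 hr and 20 hr. The atp-2 RNAi libraries stayed between 132 and 635 TPM at every time.

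The deposited tables of the authors carry their own calls, from a test that the sources used here do not name. At 0 hr the authors' deposited table listed 11331 genes (6112 higher, 5219 lower) and at 20 hr 12234 (7372 higher, 4862 lower). The smallest listed log2 ratios were 1.0001 and 1.0003 in size, and the largest p-values of the unnamed test 0.05 and 0.0498. Of the listed genes, 10956 and 11847 had a q-value under 0.05. The limma calls above had no minimum fold, so their counts are not like for like. For the unreplicated pairs, the authors' deposited table listed 364 genes at 24 hr, of which 6 had a q-value under 0.05, 568 at 36 hr, of which 22 had one, and 2040 for 54 hr against 48 hr, of which 581 had one. The log2 ratio of atp-2 in the authors' deposited table was -4.02 at 0 hr and -3.22 at 20 hr.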

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

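Of the tests reported here, those of delayed development and of a younger stage for the neuronal genes were planned before their result was seen, and the tests of the relative scale of TPM, the loss of the germline share and the 5 tests on mitochondrial transcripts were chosen only after it. The results that follow stand out because the change after atp-2 RNAi differed between 0 hr and 20 hr by a limma interaction test with Benjamini-Hochberg adjustment. Values are the change at 20 hr minus the change at 0 hr on the log2 scale.

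Some collagens and sperm genes gave the most positive differences. The collagen genes col-81 (10.84), col-139 (10.62) and col-129 (10.33) and the cuticle gene bli-6 (8.66) were lower after atp-2 RNAi at 0 hr. At 20 hr bli-6 was higher (4.3) and so was col-129 (1.73), while col-139 did not pass (1.28, limma adjusted p = 0.0607). The sperm genes ssq-4 (8.48) and msp-59 (8.29) turned from lower to higher. The most negative differences were in pud-1.2 (-3.75), pud-2.1 (-3.70), C27A7.8 (-3.47), pud-3 (-3.40), pud-2.2 (-3.20) and col-158 (-3.19). The pud genes have near-identical copies, as have the msp and collagen genes, so their single values are uncertain.

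Gene lists differed too, with camera adjusted p below 0.05 and, with an estimated correlation, adjusted p = 0.769 or more. Major sperm proteins had a median difference of 6.65 (28 of 28 more positive) and other sperm genes 5.51 (23 of 26, camera adjusted p = 1.88e-16). Collagens were at 2.07 (74 more positive and 18 more negative of 157; 83 and 21 adjusted over the list alone) and molting genes at -1.21 (3 and 9 of 33; 3 and 8 adjusted over the list alone). Body wall muscle was at 1.71 (17 of 24), intestine at 0.59 (12 of 25), FMRFamide-like peptides at 1.25 (22 of 30), other neuropeptide-like genes at 1.16 (32 of 52), dense-core vesicles at 0.84 (7 of 14) and acetylcholine and GABA at 0.64 (12 of 25). UDP-glucuronosyltransferases were at 0.84 (28 of 56), glutathione S-transferases at 0.67 (14 of 37), ABC transporters at 0.63 (15 of 37) and epidermal antimicrobial peptides at 0.79 (8 of 19). Other nuclear ATP synthase genes were at 0.42 (7 of 15), the nuclear electron transport chain at 0.39 (14 of 34), the mitochondrial genome at 0.55 (6 of 12), the vacuolar ATPase at 0.59 (16 of 22) and ribosomal proteins at 0.28 (13 of 80, 2 adjusted over the list alone). More negative were the endoplasmic reticulum unfolded protein response at -0.62 (8 of 16), histones at -0.91 (29 of 60), the proteasome at -0.76 (31 of 33) and RNA interference machinery at -0.58 (19 of 36). These counts depend on the scaling. After a shift of all libraries to a common median, 0 of 12 mitochondrial genome genes were more positive, 4 of 15 other ATP synthase genes, 7 of 22 vacuolar ATPase genes (2 more negative), 4 of 34 electron transport chain genes (1 more negative) and 2 of 80 ribosomal protein genes, and all these medians stayed above 0. Molting genes had 17 of 33 more negative in place of 9. Camera was not run for the difference after that shift.

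The levels behind these differences moved in controls, after atp-2 RNAi or in both. From 0 hr to 20 hr the median of major sperm proteins moved by -5.82 in controls and 0.88 after atp-2 RNAi, and that of other sperm genes by -4.66 and 0.63. Collagens moved by -1.59 and 0.11 and FMRFamide-like peptides by -1.48 and -0.26. Molting genes moved more after atp-2 RNAi (-0.38 in controls and -1.61), as did histones (0.21 and -0.45). These are levels across separately made tables.

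The first pattern weighed is the fall of germline, yolk and sperm genes and the rise of molting genes at 0 hr. A common factor per library, as the relative scale of TPM would give, moves all genes alike and so cannot give both the falls and the rises. The pattern was chosen because it holds both, so this test could not have come out otherwise. How far the relative scale adds to the rises stays open. The 127 genes of the germline, oocyte, yolk and sperm lists had an upper quartile of -3.52, below the lower quartile of the 13934 other genes (-1.2), and the 33 molting genes a lower quartile of 2.63, above the upper quartile of the others (1.39). Delayed development stays open. Across 14094 genes, which are not independent replicates, the 0 hr change correlated at r of 0.46 with the control ratio of 36 hr to 48 hr, between the bounds set for and against it, and that ratio rests on 1 library each. It also leaves out the difference between the controls of 48 hr and 0 hr, which correlated at 0.675 to 0.742. The treated libraries of 0 hr correlated at 0.918 to 0.935 with the single controls of 24 hr and 36 hr. With the controls of 0 hr they correlated at 0.533 to 0.608, which goes with a younger stage. The treated libraries of 20 hr correlated at 0.886 to 0.927 with the controls of 24 hr and 36 hr and at 0.555 to 0.572 with the controls of 20 hr. Treated worms at 0 hr and 20 hr may thus be younger in stage than their controls, which cannot be told apart from a direct effect on these genes.

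The second pattern is the rise of neuronal genes at 0 hr. A loss of the germline share, which would raise other somatic lists alike, stays open. The 300 neuronal genes had a median change of 1.33 (quartiles 0.53 and 1.90). The 25 intestine genes had a lower median of 0.32 (two-sided permutation test, p = 0.00059), but their upper quartile of 1.40 lies within the neuronal quartiles. The 23 body wall muscle genes outside the neuronal lists, with a median of 1.04 (two-sided permutation test, p = 0.27), and the 11 pharynx genes, with 1.84 (p = 0.17), did not pass. These tests permuted genes, which are not independent replicates, so their p-values do not measure the spread between libraries. A younger stage stays open too, since the 228 neuronal genes called higher, with a median rise of 1.64, had a median control ratio of 36 hr to 48 hr of 0.53, between the bounds. Whether single neurons changed their expression was not measured in whole worms.

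The third pattern is the higher level of mitochondrial genome transcripts in every comparison. A younger stage of the treated worms is argued against for 0 hr and 20 hr alone, as the lowest share of TPM in these atp-2 RNAi libraries was 3.9% and the highest of 9 controls of every time 1.8%. For the unreplicated pairs it stays open. Their atp-2 RNAi shares of 0.98%, 1.27% and 1.79% exceed the controls of the pairs (0.52%, 0.46% and 0.72%), so no control of an earlier time in the pairs reaches those of 36 hr and 54 hr, which goes against it. They lie below the highest control share, of 0 hr, a group with yolk transcripts, and each rests on 1 library, with no control before 24 hr among the pairs. Loss of germline RNA, which would raise somatic lists alike, is argued against as the whole cause in the unreplicated pairs. There the mitochondrial medians were 1.14, 1.61 and 1.54 and those of body wall muscle 0.17, 0.09 and -0.18, and the lower quartile of the former lay above the upper quartiles of the intestine, muscle and pharynx lists by 0.52 or more. The nearest was the set of neuronal genes for 54 hr against 48 hr, with an upper quartile of 1.39 against 1.46. At 0 hr and 20 hr it stays open, since the quartiles overlapped (smallest distance -1.44) and muscle had medians of 1.05 and 2.74 against 1.5 and 2.17. Better recovery of RNA without long poly(A) tails stays open too, because histones went both ways, with medians of 0.32, -0.46 and -0.28 in the pairs and 1.71 and 1.43 at 0 hr and 20 hr. The germline list lay at -1.12 and -1.42 in the last 2 pairs, where the histone medians were negative. It also lay at -3.54 and -3.82 at 0 hr and 20 hr, where the histone medians were positive. A link between histone and germline levels was not tested. The bounds of the tests on a younger stage here, germline RNA, poly(A) tails, the germline share and the scale of TPM were replaced after their values were seen. The bounds first written had been met, against a younger stage (on 3 single controls), against germline RNA and poly(A) tails (each on 1 library pair), against the germline share (on the intestine list alone) and against the scale of TPM (on a median shift too small to test it). Of these, poly(A) tails, the germline share, germline RNA at 0 hr and 20 hr and a younger stage in the pairs are left open here.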

How the results depend on the processing

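All alternatives here were planned, except camera after quantile normalization, which was added after the results were seen. Of the planned ones, among the results that answer a comparison, 124 values under an alternative stayed on the same side or within 1.5 times the reported count, 8 were weaker, 1 stronger and 3 moved, and of the values for single named genes and lists 4370 stayed the same and 85 were weaker, 61 of these under an estimated correlation. In the added one, 59 list calls stayed, pharynx at 20 hr lost its call (camera adjusted p = 0.37) and ribosomal proteins at 20 hr lost theirs and reversed (camera adjusted p = 0.266), their median going from 0.30 to -0.13 and their counts from 32 higher and 3 lower to 4 and 11.

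At 20 hr, genes called higher numbered 9342 with no filter on low values, where more genes were tested, and 3925 with a mean of at least 5 TPM, where fewer were. With that stricter filter, fewer genes were also at least 2-fold apart in unreplicated pairs, at 609 higher and 442 lower at 36 hr and 978 lower for 54 hr against 48 hr. Gene lists past the camera threshold numbered 0 with an estimated correlation at 0 hr and 0 at 20 hr, against 31 and 30 with the preset one. That alternative also sets each list against the residual degrees of freedom of a fit of 5 libraries, in place of nearly as many as there are genes. The lost calls are thus not due to correlation alone. At 20 hr the intracellular pathogen response list had an estimated correlation of 0.00382, below the preset one. Its camera adjusted p still went from 0.00302 to 0.528.

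Leaving out each library gave 5566 to 6292 higher and 5052 to 5717 lower genes at 0 hr, and 5920 to 6090 higher and 4988 to 5208 lower at 20 hr. It gave 29 to 31 lists at 0 hr and 28 to 30 at 20 hr. For the difference between both times it gave 2177 to 3194 more positive and 1380 to 3398 more negative genes. The more negative count was 1875 without control 0 hr replicate 2, 1380 without atp-2 RNAi 0 hr replicate 2, 1915 without atp-2 RNAi 0 hr replicate 3, 1964 without control 20 hr replicate 2 and 1531 without atp-2 RNAi 20 hr replicate 2. These fits have fewer samples. Single lists whose camera call ended without 1 library were oxidative stress, body wall muscle and DAF-16 targets at 0 hr without atp-2 RNAi replicate 3, collagens at 0 hr without control replicate 1, and at 20 hr intestine without atp-2 RNAi replicate 3. At 20 hr the nuclear electron transport chain and ribosomal proteins lost the call without control replicate 2, control replicate 3 or atp-2 RNAi replicate 2, after a median shift and with the replicate block. Pharynx genes lost it at 20 hr without control replicate 1, atp-2 RNAi replicate 2 or atp-2 RNAi replicate 3, with a pseudocount of 0.1 and with the replicate block. Where 1 atp-2 RNAi library is left, it is assumed to vary like the other group.

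Groups share replicate numbers 2 and 3, but the deviations of same-numbered libraries correlated at 0.028 or less at 0 hr and 0.005 or less at 20 hr. With the replicate block the counts were 6019 and 5523 at 0 hr, 6109 and 5157 at 20 hr, and 2737 and 2563 for the difference. Quantile normalization turned the sign of 8 called genes at 0 hr and 683 at 20 hr, and the cause was not tested. Alternatives that need counts were not run. At 0 hr the calls of ckb-2 and tbh-1 ended with no filter, that of ckb-2 also without atp-2 RNAi replicate 3, and that of amx-3 with a minimum of 2-fold. Depth is unknown, so what it limits cannot be stated.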

Other observations

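No test was added here, and gpd-2 and gpd-3 were named after their values were seen. Genes of the machinery of RNA interference itself were lower after atp-2 RNAi. At 0 hr 30 of 36 fell and 3 rose (the same adjusted over the list alone; median -1.69, camera adjusted p = 1.25e-05, adjusted p = 0.601 with an estimated correlation), with the Argonaute genes wago-1 at 10.4 ± 0.73 against 425 ± 59 TPM (-5.22) and hrde-1 at -5.04. At 20 hr 32 fell and 4 rose (the same adjusted over the list alone; median -2.51, camera adjusted p = 6.09e-06, adjusted p = 0.528 with an estimated correlation). Both Argonautes act in the germline, whose genes fell in the same libraries. Proteasome genes fell in 33 of 33 cases at both times (33 adjusted over the list alone; medians -0.99 and -1.81, camera adjusted p = 3.09e-07 and 1.03e-08). Their adjusted p = 0.601 and 0.528 with an estimated correlation. The subunit gene rpn-7 was at 89.8 ± 1.79 against 256 ± 27.4 TPM at 0 hr (-1.5). Histone genes rose in 50 of 62 cases and fell in 5 at 0 hr (the same adjusted over the list alone; median 1.71, camera adjusted p = 3.72e-05, adjusted p = 0.608 with an estimated correlation), while his-74 (-4.57) and his-68 (-3.87) fell.

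Paralogs of the same enzyme or ribosomal protein went opposite ways. The glyceraldehyde-3-phosphate dehydrogenase genes gpd-1 (-4.73) and gpd-4 (-5.0) fell at 0 hr and gpd-2 (1.71) and gpd-3 (1.54) rose, as at 20 hr (-5.84, -5.8, 3.78 and 3.42). Their sequences are close, so single values are uncertain. Glycolysis genes as a list rose in 7 of 21 cases and fell in 6 at 0 hr (the same adjusted over the list alone; camera adjusted p = 0.971), with a median of 0.04 that became -0.10 after a median shift. The ribosomal protein genes rpl-11.1 (-3.46 and -2.76) and rpl-11.2 (1.51 and 3.32) parted likewise at 0 hr and 20 hr. The vacuolar ATPase genes vha-18 (-4.62) and vha-7 (-2.06) fell at 0 hr. The glyoxylate cycle gene icl-1 rose to 1460 ± 136 from 28.1 ± 24.9 TPM (5.98) and the fatty acid genes acs-2 (4.87) and fat-7 (-4.24) moved apart.

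Immune and stress lists not described above were mixed. The p38 immune list rose in 19 of 25 genes and fell in 4 at 0 hr (the same adjusted over the list alone; camera adjusted p = 0.00323, adjusted p = 0.601 with an estimated correlation), led by T24E12.5 (4.8) and irg-4 (4.61). Of the lysozyme and lectin genes, clec-87 fell the most, at 2.04 ± 0.733 against 917 ± 190 TPM (-8.24). Cytosolic heat shock genes rose in 10 of 20 cases and fell in 5 (9 and 5 adjusted over the list alone; camera adjusted p = 0.909), sip-1 falling (-5.03) and hsp-17 rising (2.85). DAF-16 targets rose in 17 of 25 cases and fell in 5 (the same adjusted over the list alone; camera adjusted p = 0.028, adjusted p = 0.601 with an estimated correlation), with mtl-1 at 5.72. Other lists also hold 16 of the 27 genes of the DAF-16 list.

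Tissue lists other than neurons differed at 0 hr. Body wall muscle genes rose in 16 of 24 cases and fell in 2 at 0 hr (the same adjusted over the list alone; median 1.05, camera adjusted p = 0.0267, adjusted p = 0.741 with an estimated correlation). Intestine genes rose in 12 of 25 cases and fell in 4 (11 and 4 adjusted over the list alone; camera adjusted p = 0.163). The insulin-like peptide genes rose in 7 of 16 cases and fell in 6 (the same adjusted over the list alone; camera adjusted p = 0.623), with a median of 0.24 that quantile normalization turned to -0.03, and ins-27 at 118 ± 0.859 against 7.17 ± 2.1 TPM (3.9). Markers of all neurons and of neuron types rose in 18 of 19 cases (18 adjusted over the list alone; camera adjusted p = 0.000468, adjusted p = 0.601 with an estimated correlation).

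The treated libraries of 0 hr correlated across genes at 0.918 to 0.935 with the control libraries of 24 hr and 36 hr, and at 0.533 to 0.608 with the controls of 0 hr.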
